A study of Mus musculus with 15 samples.

How the data were processed

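Extracellular miRNAs were profiled in platelet-free plasma of male C57BL/6J wild-type mice, 24 h after a sham operation (6 libraries) or CLP (9 libraries). Per the labels' protocols, blood was spun at low and then at high speed to remove cells and platelets, and total RNA was extracted from the plasma with Trizol LS. Small RNA libraries were made with a Norgen Biotek kit by ligation of adapters to both ends, reverse transcription and indexing PCR, and the wanted band was cut from a gel, per the labels' protocols. Adapter ligation favours some end sequences, and libraries were pooled at equal molarity per the labels' protocols, so counts give relative and not absolute amounts.

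The deposited table holds read counts per mature miRNA in the unit of expected counts, not scaled for depth, in 15 columns, each mapped to 1 library by its label. The name of the deposited table gives exceRpt, a small RNA pipeline, as its source. The genome build was mm10, per the submitters' processing notes. The aligner, the mismatches allowed, trimming settings and the miRNA annotation release were not given in the sources used here. From the values, 4.56% of entries were not whole numbers, between 44 and 67 entries per library in 156 rows, as arises when reads that match several miRNAs are divided between them. Of the 1205 rows, 19 named more than 1 miRNA and were counted once, and 44 named a precursor hairpin, 0 of which were tested. Library totals ran from 5274676 to 13576481 counts, and the tested miRNAs held at least 99.97% of each. Expected counts were rounded to whole numbers before testing.

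Differential abundance was tested with edgeR 4.0.16 in R 4.3.3. miRNAs were kept by filterByExpr, libraries were scaled by TMM, and a robust quasi-likelihood F test compared the groups with no covariate, two-sided, with Benjamini-Hochberg adjustment over the 426 tested miRNAs and a threshold of 0.05. The biological coefficient of variation was 0.463. Standard errors were approximated by the size of the log2 fold change divided by the square root of F. Lists of miRNAs were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, adjusted over 15 lists with at least 3 tested members. List members can belong to more than 1 list. Library measures, the haemolysis index (pseudocount 0.5) and component scores were compared by exact two-sided permutation tests over the 5005 ways to split 15 libraries into 9 and 6. Intervals of counting error were not computed.

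Lists, preset names, tests and most alternatives were fixed before the data were examined. The miRNAs named were, by a rule fixed then, the 10 largest rises and 10 largest falls among those past the threshold with a mean of at least 10 CPM, the 5 most abundant, 21 preset names of which 20 were tested, and up to 4 members of each list past the threshold with the highest mean CPM. That rule gave 78 miRNAs. Further list members, such as miR-133b-3p, let-7g-5p and miR-219a-2-3p, were named after their values were seen. Precursor positions came from GENCODE M21 on mm10 (GRCm38), in which 1138 rows matched a precursor gene. GC content was taken from the 5' or 3' part of each hairpin as a stand-in for the mature sequence, for 393 tested miRNAs.

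The fits were tested on simulated data drawn from the means and library sizes of the real libraries, with 437 miRNAs in the test of CLP against sham. Of 93 miRNAs changed 2-fold 58.1% were called, and of 90 changed 4-fold 94.4% were called, with 1.42% of calls false. When only the neural list was raised, 1 list passed. The simulated miRNAs were drawn independently, whereas the real let-7 list had an estimated correlation of 0.30. That result therefore cannot show how often correlated lists pass by chance. Libraries were compared pairwise within each group before averaging. The lowest chi-square per degree of freedom was 284 within sham and 450 within CLP, so no library was a copy of another in its group. Chi-square was not computed between the groups, where the highest Spearman correlation of 2 libraries was 0.930. Alternatives were DESeq2 1.42.0, limma voom with quality weights, DESeq2 size factors, scaling by library size, no filter and a stricter filter, the haemolysis index as a covariate, removal of erythroid miRNAs, other forms of the list test, and leaving out each library in turn. Removal of the GC trend, leaving out CLP 1 and CLP 5 together, and use of replicates 1 to 6 alone were added after seeing the data. No library was left out of the comparison. miR-34a-5p, a preset name, was too low to be tested.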

Results

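Small RNA libraries were made from platelet-free plasma of male C57BL/6J wild-type mice taken 24 h after surgery. The mice had undergone either cecal ligation and puncture (CLP), an operation that releases gut bacteria into the abdomen and serves as a model of polymicrobial sepsis, or a sham operation. There were 6 sham and 9 CLP libraries, numbered within each group. The labels do not say that each number is a separate animal, so p-values measure the spread between these samples. Values are counts of reads assigned to mature microRNAs (miRNAs). Totals ran from 5274676 counts in sham 4 to 13576481 in CLP 3, and 426 of the 1205 miRNA entries passed the abundance filter. The mean log2 total was 22.69 ± 0.37 (SD, n = 6) in sham and 23.05 ± 0.45 (n = 9) in CLP (exact two-sided permutation p = 0.120, adjusted over 4 library measures 0.161).

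The composition of the plasma libraries differed between the groups. The red cell miRNA miR-486a/b-5p was the most abundant entry in all 6 sham libraries and in CLP 5 and CLP 6. In CLP 1, 4, 7, 8 and 9 the most abundant was miR-10a-5p, whose gene lies among the HoxB genes, and in CLP 2 and CLP 3 it was miR-22-3p. After thinning every library to the smallest total, 643 ± 9.97 miRNAs (SD, n = 6) were detected in sham and 682 ± 14.5 (n = 9) in CLP, a difference of 39 miRNAs (exact permutation p = 0.000599, adjusted 0.00240). The most abundant entry took 28.3% ± 12.7 of the counts in sham and 21.2% ± 5.22 in CLP (exact permutation p = 0.182, adjusted 0.182), a difference of -7.13 percentage points that was -3.60 without sham 2. The 10 most abundant took 71.6% ± 2.18 and 74.1% ± 2.02 (exact permutation p = 0.0418), which did not pass after adjustment (0.0835).

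The first principal component of log2 CPM (counts scaled to library size as adjusted by TMM) held 54.6% of the variance and separated the groups. Sham scores averaged -17.0 ± 2.16 (SD, n = 6) and CLP scores 11.3 ± 6.18 (n = 9; exact permutation p = 0.0002, the smallest that 5005 permutations can give). CLP 5 lay nearest to sham, at -1.73, where the other CLP scores began at 7.94. The second component held 9.94% of the variance and did not differ between the groups (exact permutation p = 0.977). The median Spearman correlation across miRNAs was 0.960 between sham libraries, 0.945 between CLP libraries and 0.878 between libraries of different groups.

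**Figure D1:**
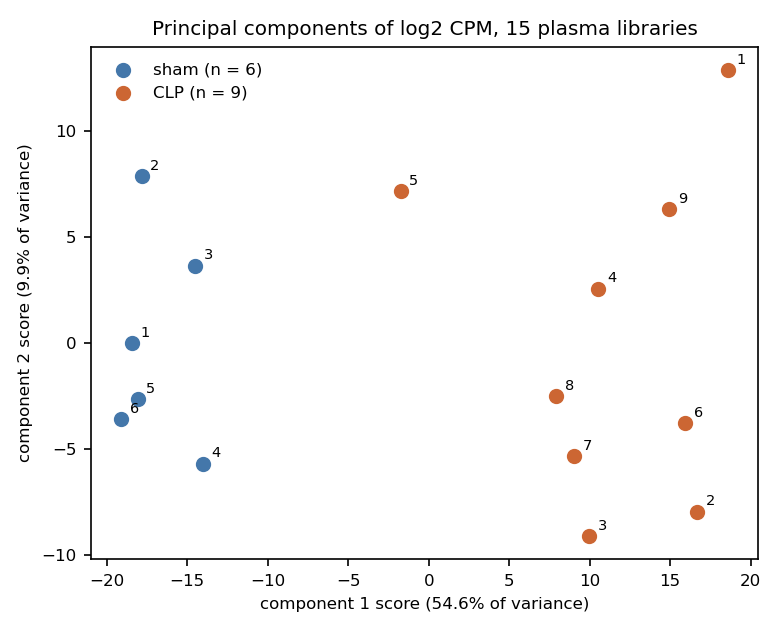
Scores of the 15 libraries on the first and second principal components of log2 CPM over 426 miRNAs, without units, with the replicate number beside each point. The 6 sham libraries lie between -19.1 and -14.0 on component 1, CLP 5 lies at -1.73 and the other CLP libraries lie between 7.94 and 18.6.

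The comparison of CLP with sham asked which extracellular miRNAs differ in plasma during polymicrobial sepsis. Among miRNAs with a mean of at least 10 CPM over the 15 libraries, the largest rise was that of miR-1a-3p, made in heart and skeletal muscle, which went from 1081 ± 1370 CPM (SD, n = 6) to 18065 ± 10219 (n = 9). The pancreas-enriched miR-217-5p came next, and then miR-206-3p, made in skeletal muscle, which went from 210 ± 198 to 1616 ± 899 CPM. The myeloid miR-223-5p, the tumour-suppressor family members let-7a-5p and let-7f-5p, and miR-155-5p, which activated immune cells induce, also rose. Some rarer miRNAs changed by more than some of those ranked. The largest falls within the limit were in miR-214-3p, which went from 531 ± 223 to 14.1 ± 13.8 CPM, and in miR-877-5p, miR-574-3p, miR-455-3p and the epithelial miR-205-5p. Among abundant miRNAs, miR-191-5p fell from 37342 ± 3797 to 5450 ± 2419 CPM, and miR-22-3p rose from 29869 ± 7318 to 114353 ± 61576 CPM.

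By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 201 of the 426 tested miRNAs differed at an adjusted p under 0.05, 108 of them higher and 93 lower in CLP. At least 4-fold changes were found for 24 of the higher and 30 of the lower ones. Of the 426 tested miRNAs, 84 were among the 201 and had every CLP library beyond the range of the 6 sham libraries. Chance alone would so separate 0.0400% of miRNAs not picked by their difference. When counts were scaled by library size alone, the median log2 fold change shifted by -0.23 and the split became 90 higher and 126 lower, so directions are relative to the scaling used.

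The log2 fold change of miR-1a-3p was 4.06 ± 0.74 (SE; edgeR adjusted p = 0.000247), with 8 of 9 CLP libraries above every sham library. It lay between 3.75 without sham 2 and 5.0 without sham 4, and was 3.43 once a GC trend between libraries was removed. Its precursors lie on chromosome 2 (180389048 to 180389124, plus strand, mm10) and on chromosome 18 (10785481 to 10785552, minus strand), the latter in an intron of the Mir133a-1 host gene. The precursor of miR-206-3p, at chromosome 1, 20679010 to 20679082, lies in an exon of a long noncoding RNA gene. The change of miR-206-3p was 2.95 ± 0.50 (edgeR adjusted p = 0.000146), and between 2.63 without CLP 3 and 3.56 without sham 4. The rise of miR-217-5p (3.56 ± 0.83, edgeR adjusted p = 0.00199) was uneven: 6 CLP libraries exceeded every sham library, up to 402 CPM in CLP 6, while CLP 1, CLP 5 and CLP 7 held 13.1, 12.9 and 15.9 CPM against a sham range of 7.61 to 17.7. Its call was lost with the replicate number as a block over 12 libraries (2.24, edgeR adjusted p = 0.0509). For miR-381-3p, from the imprinted Dlk1-Dio3 region, the change was 2.92 ± 0.54 (edgeR adjusted p = 0.000331), and 2.22 without CLP 2, which held 407 CPM. All 9 CLP libraries exceeded every sham library for miR-223-5p (2.78 ± 0.28), let-7a-5p (2.52 ± 0.25), let-7f-5p (2.35 ± 0.31), miR-340-5p (2.29 ± 0.27), miR-129-5p (2.64 ± 0.36) and miR-708-3p (2.50 ± 0.30), with edgeR adjusted p from 3.64e-07 to 8.47e-06. Once the GC trend was removed, the change of miR-340-5p was 1.57.

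The fall of miR-214-3p was -5.22 ± 0.57 on the log2 scale (SE; edgeR adjusted p = 1.92e-06). Its precursor, at chromosome 1, 162223368 to 162223477, lies in an exon of Dnm3os, a noncoding transcript antisense to Dnm3. The change was -4.28 ± 0.25 for miR-574-3p (edgeR adjusted p = 3.57e-10), whose precursor lies in an intron of Fam114a1 (chromosome 5, 64970318 to 64970395). It was -4.35 ± 0.71 for miR-877-5p, -3.78 ± 0.34 for miR-455-3p and -3.51 ± 0.33 for miR-205-5p. For miR-423-5p it was -2.97 ± 0.57, and between -3.73 without CLP 5 and -2.83 without CLP 9. For miR-877-5p it lay between -5.13 without CLP 5 and -4.17 without CLP 9. miR-191-5p (-2.78 ± 0.28), miR-184-3p (-2.66 ± 0.49), miR-30b-5p (-2.30 ± 0.20) and miR-215-3p (-2.23 ± 0.27) completed the 10 largest falls among miRNAs with a mean of at least 10 CPM, and in each of the 10 all 9 CLP libraries lay below every sham library. The median GC content of the hairpin arm was 47.7% for higher and 54.1% for lower miRNAs.

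**Figure D2:**
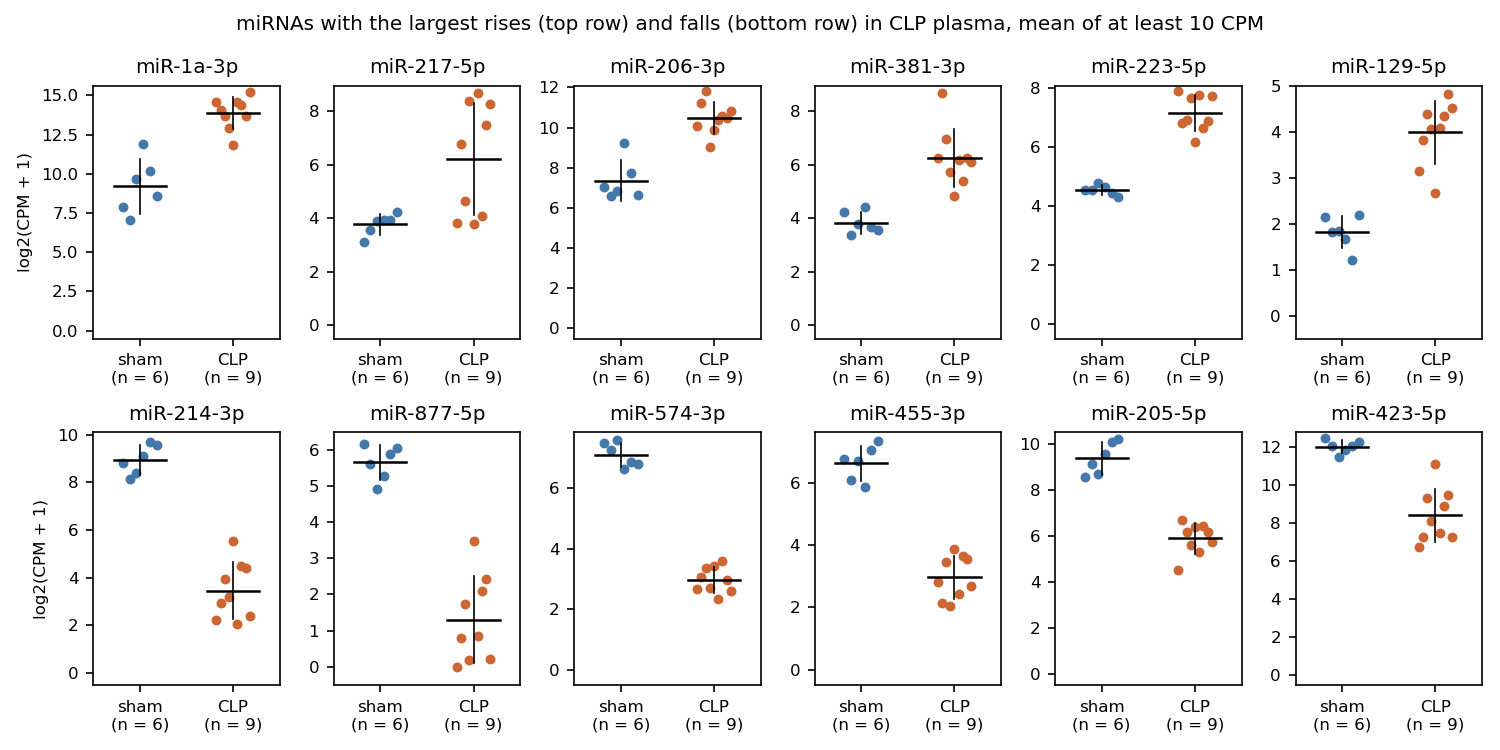
Abundance, as log2(CPM + 1), of the 6 miRNAs with the largest rises (top) and the 6 with the largest falls (bottom) among those with a mean of at least 10 CPM, in 6 sham and 9 CLP libraries, where points are libraries, horizontal lines means and vertical lines 1 SD either side. For miR-217-5p, CLP 1, CLP 5 and CLP 7 lie at the sham level, and for each fall all 9 CLP points lie below the sham points.

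Of the most abundant miRNAs, miR-10a-5p rose by 1.14 ± 0.21 on the log2 scale (SE; edgeR adjusted p = 0.000194) and miR-22-3p by 1.94 ± 0.34 (edgeR adjusted p = 0.000153). Once the GC trend was removed, miR-10a-5p was at 0.65 (edgeR adjusted p = 0.0107) and miR-22-3p at 2.25 (2.3e-05). The changes of miR-486a/b-5p (-0.70 ± 0.33, edgeR adjusted p = 0.0867), miR-10b-5p (0.43 ± 0.21, 0.101) and the smooth muscle miRNA miR-143-3p (-0.07 ± 0.42, 0.893; 0.58 without sham 6, 0.151) did not pass. That of miR-486a/b-5p did pass with library size scaling (0.0200), with limma voom (0.0161), with no filter (0.0226), with CLP 1 and CLP 5 both left out (0.0235), and without sham 4, sham 6, CLP 3 or CLP 5, where it was -1.05 without CLP 5 (0.00372). With the GC trend removed, the change of miR-486a/b-5p shrank to -0.25 (edgeR adjusted p = 0.529). The change of miR-10b-5p passed with limma voom (0.0236) and with CLP 1 and CLP 5 both left out (0.0462). It was 0.09 with the GC trend removed (edgeR adjusted p = 0.762), and between 0.27 and 0.53 on leaving out 1 library. Of the named miRNAs, 25 held a value that was not a whole number, as arises when shared reads are divided between similar miRNAs. A whole number does not show that no reads were shared. How many reads were divided was not measured, so the values of these 25 are uncertain by an unknown amount. Among them were let-7a-5p (15 of 15 libraries), let-7c-5p (13), miR-30b-5p (12), miR-26a-5p and miR-146b-5p (9 each), miR-10a-5p, miR-10b-5p and miR-23a-3p (8 each) and miR-133a-3p (7).

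miRNAs of striated muscle moved apart. Of 8 tested members, 4 rose and none fell, over all tested and likewise when adjusted over the list alone (4 and 0). miR-1a-3p and miR-206-3p rose as above. miR-208b-3p, from an intron of Myh7, was read in 1 of 6 sham libraries and went from 0.129 ± 0.315 to 3.88 ± 3.35 CPM. The change of miR-208a-3p (1.24 ± 0.62, edgeR adjusted p = 0.110) did not pass. The call of miR-499-5p (1.94 ± 0.67, edgeR adjusted p = 0.0244) was lost without sham 1 (0.0559) or sham 6 (0.0560), with no filter (0.0714), with the replicate number as a block (0.0957) and with replicates 1 to 6 alone (0.0783). By contrast the change of miR-133a-3p, made from the same transcripts as miR-1a-3p, was 0.54 ± 0.50 (edgeR adjusted p = 0.400) and that of miR-133b-3p, the partner of miR-206-3p, -0.60 ± 0.51 (0.348). On leaving out 1 library the change of miR-133a-3p lay between 0.25 (without sham 2) and 1.06 (without sham 4) and never passed. The list as a whole did not pass (camera adjusted p = 0.0829), although it did without sham 4 (0.0260) or without CLP 5 (0.0445).

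Among liver miRNAs, 3 of 8 tested members rose and 1 fell, and the counts adjusted over the list alone were the same. The hepatocyte miRNA miR-122-5p was 5995 ± 4359 CPM in sham and 15721 ± 24545 in CLP, a log2 change of 1.39 ± 0.76 that did not pass (edgeR adjusted p = 0.139). CLP 1 held 79178 CPM of it, and without CLP 1 the change was 0.35. miR-148a-3p rose by 1.79 ± 0.24 and miR-193a-3p by 1.49 ± 0.36, while miR-215-5p, a relative of miR-192-5p, fell by 2.13 with an SE of 0.30. Of these, miR-193a-3p was scarce, at 2.83 ± 1.56 CPM in sham and 7.95 ± 2.94 in CLP. The call of miR-194-5p (0.84 ± 0.33, edgeR adjusted p = 0.0423) was lost on leaving out any library other than sham 5, CLP 3, CLP 4 or CLP 6, with adjusted p up to 0.115, and under most other settings, with adjusted p up to 0.176 with the replicate number as a block. Without CLP 1 the change of miR-194-5p was 0.49. The list did not pass (camera adjusted p = 0.530). Among pancreas miRNAs 3 of 6 rose and none fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.385), with miR-217-5p, miR-148a-3p and miR-7a-5p the members that rose, and the islet miRNA miR-375-3p at 0.67 ± 0.36 (edgeR adjusted p = 0.133), or 0.97 (0.0265) with the GC trend removed. The other members, miR-216a-5p (-0.35 ± 0.69, 0.702) and miR-216b-5p (-0.42 ± 0.94, 0.739), did not pass.

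Of 10 tested red cell miRNAs 1 rose and 1 fell, with the same counts adjusted over the list alone. miR-451a, processed in maturing red cells, fell by 1.28 with an SE of 0.32 (edgeR adjusted p = 0.00313), and miR-20b-5p rose from 0.397 ± 0.398 to 2.0 ± 1.02 CPM. miR-144-3p, whose precursor lies beside that of miR-451a on chromosome 11, did not pass (-0.10 ± 0.38, edgeR adjusted p = 0.838). Nor did miR-16-5p (0.09 ± 0.23, edgeR adjusted p = 0.778). The haemolysis index, log2 of miR-451a over miR-23a-3p, was -0.44 ± 0.67 (SD, n = 6) in sham and -1.41 ± 0.99 (n = 9) in CLP (exact permutation p = 0.0585), and it was highest in CLP 5 at 0.72. Without CLP 5 the difference was -1.24 (exact permutation p = 0.00633). With miR-103-3p as the denominator it was -3.13 (exact permutation p = 0.0002), but miR-103-3p itself rose by 1.72 ± 0.37 (edgeR adjusted p = 0.000824), a change looked up after the values were seen. The list did not pass (camera adjusted p = 0.739).

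Inflammation-induced miRNAs mostly rose: 7 of 12 tested were higher and 1 lower, over all tested and adjusted over the list alone, but the list did not pass as a whole (camera adjusted p = 0.292). miR-155-5p rose by 2.04 ± 0.37 (SE; edgeR adjusted p = 0.000188), from 2.22 ± 1.22 to 9.13 ± 3.31 CPM, and miR-21a-5p by 1.28 ± 0.23 (0.000186). The clustered pair miR-221-3p and miR-222-3p went opposite ways, at 1.06 ± 0.20 and -1.24 ± 0.18. The feedback regulators of Toll-like receptor signalling did not pass, miR-146a-5p at -0.15 ± 0.28 (edgeR adjusted p = 0.692) and miR-146b-5p at -0.32 ± 0.20 (0.197), although the latter passed with library size scaling (0.0491).

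Of 9 myeloid miRNAs 3 rose and none fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.152). These were miR-223-5p, miR-155-5p and the scarce miR-147-3p, which went from 0.916 ± 0.604 to 5.71 ± 2.71 CPM. By contrast miR-223-3p, from the other arm of the miR-223 hairpin, was at 0.36 ± 0.21 (edgeR adjusted p = 0.157). Of 12 lymphocyte miRNAs 3 rose and 4 fell, and 3 rose and 5 fell when adjusted over the list alone (camera adjusted p = 0.782). miR-29a-3p rose by 1.47 ± 0.23, and miR-342-3p and miR-26a-5p changed by -0.82 ± 0.21 and -0.83 ± 0.20. Once the GC trend was removed, these changes were 0.94, -0.81 and -0.63. The call of miR-181a-5p (0.40 ± 0.16, edgeR adjusted p = 0.0465) was lost on leaving out any 1 of the 15 libraries and under most other settings, with adjusted p up to 0.422 under library size scaling. The fall of miR-150-5p, abundant in mature lymphocytes (-0.82 ± 0.33, edgeR adjusted p = 0.0480), was lost without sham 1, 2, 3 or 5 or CLP 1 or 7, with adjusted p up to 0.0712, and without CLP 1 and CLP 5 together (0.0645). It was also lost with the GC trend removed (-0.49, 0.234), with the replicate number as a block (0.137) and with replicates 1 to 6 alone (0.129). The other arm of that hairpin, miR-150-3p, looked up after the values were seen, was at -1.12 ± 0.28 (edgeR adjusted p = 0.0032). Of 10 platelet miRNAs 3 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.782). miR-24-3p rose by 0.84 ± 0.18, and miR-191-5p and miR-151-3p changed by -2.78 ± 0.28 and -1.05 ± 0.20. The call of miR-199a/b-3p (-0.60 ± 0.21, edgeR adjusted p = 0.0219) was lost without sham 5 (0.0847).

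Of 12 vascular miRNAs 4 rose and 2 fell, and 5 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.530). Smooth muscle miR-145a-5p rose by 1.61 ± 0.40, miR-125b-5p changed by -1.19 ± 0.35, and the endothelial miR-126a-3p (-0.42 ± 0.22, edgeR adjusted p = 0.129) did not pass, but did under 5 other settings, among them library size scaling (0.0327), and without CLP 9 (0.0400). Of 16 epithelial miRNAs 3 rose and 6 fell, as adjusted over the list alone. miR-205-5p and miR-215-5p fell, miR-183-5p changed by -1.45 ± 0.20 and miR-200a-3p rose by 1.04 ± 0.25. The median of this list was 0.18 but its mean -0.39, with camera's direction down (adjusted p = 0.385). Of 9 neural miRNAs 4 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.530), with miR-128-3p at 1.30 ± 0.25 and miR-7a-5p at 1.53 ± 0.27. The member that fell, miR-219a-2-3p (-3.44 ± 0.62), was scarce and went from 3.53 ± 2.10 to 0.283 ± 0.353 CPM. Of 4 stress and hypoxia miRNAs 1 rose over all tested and 0 adjusted over the list alone (camera adjusted p = 0.782), and the hypoxia-induced miR-210-3p was at -0.05 ± 0.31 (edgeR adjusted p = 0.898).

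The let-7 family was the only one of 15 lists to pass the list test. Of 9 tested members 5 rose and none fell, and 6 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.0225). That call was lost without sham 6 (adjusted p = 0.0509), and in every list the adjusted p = 0.808 with an estimated correlation. let-7a-5p and let-7f-5p rose most, let-7d-5p by 1.51 ± 0.31 and let-7c-5p by 1.12 ± 0.24, while let-7g-5p was at 0.25 ± 0.28 (edgeR adjusted p = 0.485). In the imprinted Dlk1-Dio3 cluster on chromosome 12, 17 of 33 tested members rose and 5 fell, and 19 rose and 5 fell adjusted over the list alone. miR-381-3p and miR-136-3p (1.67 ± 0.34) rose and miR-541-5p changed by -1.11 ± 0.20. The cluster had a camera adjusted p of 0.0829, which was 0.0268 without sham 4 and 0.0311 without CLP 5. In the miR-17 clusters and their relatives 4 of 14 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.530), with miR-25-3p at 1.17 ± 0.27, miR-20a-5p at 1.76 ± 0.35 and miR-93-3p at -1.04 ± 0.29, whose call was lost with the haemolysis index as a covariate (edgeR adjusted p = 0.0524). The call of miR-17-5p (0.94 ± 0.35, edgeR adjusted p = 0.0347) was lost on leaving out any of 10 of the 15 libraries, with adjusted p up to 0.134, and under most other settings, with adjusted p up to 0.166 with the GC trend removed.

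**Figure D3:**
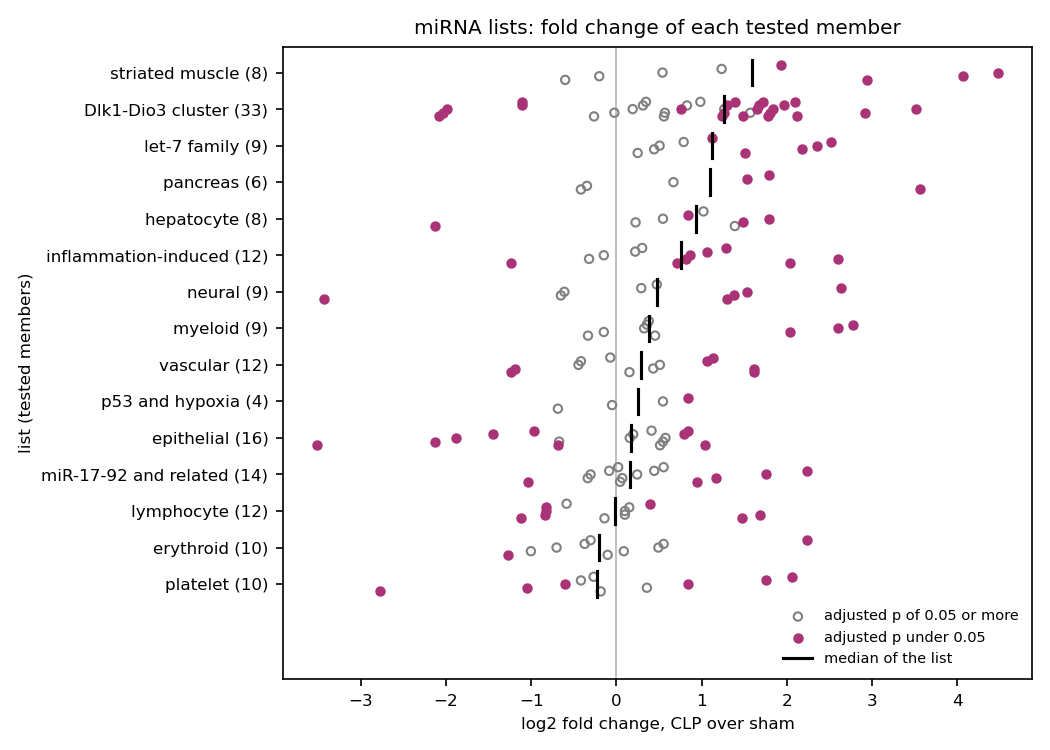
Log2 fold change (CLP over sham) of each tested member of 15 miRNA lists, with filled points at an edgeR adjusted p under 0.05, open points otherwise and a bar at the list's median. Members of the let-7 family reach from 0.25 to 2.52 and those of the epithelial list from -3.51 to 1.04.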

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

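The tests of library depth against GC content, of the muscle ratio and of a wrong label for CLP 5, and the removal of the GC trend, were chosen only after the results were seen. Single libraries that lay far from the rest of their group were found in 10 of 170 groups of values examined, where chance gives about 1 in 20. In CLP 1, miR-125b-5p lay low at a log2 CPM of 10.49 and miR-194-5p lay high at 8.53. In CLP 5, miR-145a-5p (10.47) and miR-24-3p (13.61) lay low, and the most abundant miRNA took 34.0% of the counts, the highest share in CLP. In CLP 7, miR-143-3p lay high at 16.27, and in CLP 2 miR-541-5p lay high at 9.09. In sham 1, miR-215-3p lay high at 6.93 and miR-30b-5p low at 8.56, and in sham 6 miR-208b-3p was at 0.0236, the only sham library with reads of it.

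The count of 201 differential miRNAs was compared with other splits of the 15 libraries into 9 and 6. Of 100 splits, 1 gave as many, the real one, so chance is argued against for the count, at no finer than 1 in 100. The column labels number all sham libraries before all CLP libraries, so the splits cannot tell the operation from library order. The highest of the other splits gave 88, in a split that exchanged CLP 3 and sham 2 and left the other libraries in place. For the list test, 92 of 100 splits gave at least as many lists as the real 1, with up to 8 in other splits, so chance cannot be excluded for the let-7 family.

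CLP libraries held relatively fewer reads from GC-rich hairpin arms than sham libraries. A slope on GC percent was fitted to log2 CPM less each miRNA's mean over the 15 libraries. Its sign is therefore relative to that mean. The slope was 0.022 ± 0.0075 (SD, n = 6) in sham and -0.0147 ± 0.0160 (n = 9) in CLP (exact permutation p = 0.0002, the smallest possible). It was lower in all 9 CLP libraries than in any sham library. A linear trend on hairpin-arm GC is argued against as the whole cause of the calls. After its removal 88.8% (167) of the 188 differential miRNAs with a GC value kept call and direction. In simulated libraries with a GC slope of -0.04 in CLP and no other change, 2 of 428 miRNAs were called, so its removal could end few calls. Hairpin-arm GC stands in for the mature sequence, and a bias set by the mature sequence or its ends was not tested. Within CLP the slope rose with depth (rho = 0.83, exact permutation p = 0.00827, adjusted 0.0125; Pearson r = 0.758, p = 0.0125, adjusted 0.0125; r = 0.694 without the 2 libraries farthest in total; 2 relations), which is consistent with a part set by depth. Depth does not account for the difference between the groups, which was -0.0448 (SE 0.00578) at equal depth against -0.0367 without that term, so a bias in handling or ligation and a biological change of content stay open, both untested.

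miR-1a-3p and miR-206-3p rose without miR-133a-3p and miR-133b-3p, which share their transcripts. Log2 of miR-1a-3p over miR-133a-3p differed by 3.79 between the groups and that of miR-206-3p over miR-133b-3p by 3.65 (exact permutation p = 0.0002 each, the smallest possible). The plasma thus did not keep its sham proportions. The ratios in muscle tissue were not measured, so release of muscle RNA in the proportions of muscle stays open. The gap between miR-1a-3p and miR-133a-3p was 2.81 after removal of the GC trend, and with each library left out the rise of miR-1a-3p was at least 3.75, so neither that trend nor 1 library was the whole cause. Differences in stability, in packaging or in release between muscle types may contribute as hypotheses, and none of them was tested.

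CLP 5 lay nearest to sham on component 1. Its score was 12.3 above the highest sham score, more than the whole sham range of 5.06, which argues against a sham library under a CLP label. It had the highest haemolysis index. With erythroid miRNAs left out it still lay 9.29 below the lowest other CLP score (SD of the others 4.02), so the listed miRNAs did not themselves set its place. The list holds 10 of the 426 tested miRNAs, and its removal moved the score only from -1.73 to -1.52. It therefore cannot decide whether red cell RNA at large had a part. A milder response in that sample may account for the place of CLP 5, which no label allows to be tested.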

How the results depend on the processing

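Removal of the GC trend, leaving out CLP 1 and CLP 5 together and use of replicates 1 to 6 alone were chosen after seeing the data. Without an abundance filter 140 miRNAs were higher and 167 lower, and with a filter of 10 CPM in 6 libraries 71 were higher and 70 lower, where 254 miRNAs were tested. Leaving out 1 library gave 95 to 104 higher and 82 to 110 lower miRNAs. The replicate number as a block gave 71 higher and 81 lower over 12 libraries, against 87 and 92 without it on the same libraries. Deviations of same-numbered libraries correlated at -0.15 to -0.03 and none was best matched to its own number, so the numbers share no visible pairing. Lists past the threshold numbered 0 with an estimated correlation, 2 without CLP 1 and CLP 5, and 0 (without sham 6) to 3 (without sham 4 or CLP 5) on leaving out 1 library. The haemolysis index differed by -3.13 with miR-103-3p, which itself rose, as the denominator (exact permutation p = 0.0002, the smallest possible) and by -1.24 to -0.83 on leaving out 1 library, 4 of which moved it past the threshold. The log2 total differed by 0.28 to 0.49 on leaving out 1 library, and by 0.63 with all libraries when the most abundant miRNA was not counted (exact permutation p = 0.0178). The share of the most abundant entry differed by -9.45 (without sham 5) to -3.60 (without sham 2) percentage points on leaving out 1 library. The share of the 10 most abundant differed by 1.81 to 3.11 percentage points on leaving out 1 library, and the unadjusted p was 0.05 or more for 10 of 15. Apart from the fit without the block on the same 12 libraries, no cause of these changes was tested. For the named miRNAs, 855 of 917 results under other settings kept their side of the threshold, 48 lost and 14 gained a call, and on leaving out 1 library 1105 of 1158 kept theirs. No called result reversed, and 22 of the 408 that were uncalled in both fits changed sign. With the haemolysis index as a covariate miR-93-3p and miR-127-3p were among the calls lost.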

Other observations

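The comparison of hairpin arms was chosen only after the results were seen. The 2 arms of a hairpin come from 1 transcript, and their ratio was compared between the groups for the 93 hairpins with both arms tested. The ratio differed for 46 (exact permutation tests, Benjamini-Hochberg adjusted p under 0.05). In 9 hairpins the arms were called in opposite directions and in 19 in the same direction. For miR-574, log2 of the 5p over the 3p arm went from -4.45 ± 0.49 (SD, n = 6) to 0.73 ± 0.69 (n = 9; exact permutation p = 0.0002, the smallest possible, adjusted 0.00124), as miR-574-3p fell by 4.28 and miR-574-5p rose by 1.02. For miR-191 it went from 8.23 ± 0.26 to 4.50 ± 0.51, with miR-191-3p up by 0.84, and for miR-423 from 2.62 ± 0.08 to -1.41 ± 1.39, with miR-423-3p at 0.44 (edgeR adjusted p = 0.122).

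Arms of other hairpins also parted, by the same tests. In the Dlk1-Dio3 cluster, miR-434-5p changed by -2.04 and miR-434-3p by 1.72, although the call of miR-434-3p was lost with the haemolysis index as a covariate (edgeR adjusted p = 0.0599) and with the replicate number as a block (0.0684). miR-221-5p changed by -0.81 and miR-221-3p by 1.06, whereas in its cluster partner miR-222-5p rose by 1.24 and miR-222-3p changed by -1.24. For miR-223, log2 of the 5p over the 3p arm went from -3.68 ± 0.23 to -1.32 ± 0.31. Across the 93 hairpins, which are not independent replicates, the gap in fold change between arms and their gap in GC content had a Spearman rho of -0.18.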
